A study of Mus musculus with 20 samples.

How the data were processed

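Gene expression was measured by RNA sequencing in 20 libraries of immortalised mouse kidney epithelial cells (strain C57BL/6J), in 4 groups of 5. Groups and replicate numbers were taken from the sample titles and the genotype labels. Per the labels' protocols, the cells were grown in serum-supplemented DMEM with added uridine, total RNA was purified on columns, and libraries followed standard Illumina procedures. The labels do not say whether the 5 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Nor do they say from which clone the Rec cells were made, or which part of Fh1 was deleted.

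The authors deposited counts: 1 table per library with a whole-number read count for each Ensembl gene, not normalized, followed by 5 summary lines for reads given to no gene. Per the submitters' processing notes, the genome build was GRCm38 and the tools were TopHat2 2.0.4, HTSeq 0.5.3p9 and DESeq 1.10.1. The role of each tool, the annotation release, the strand setting and any read filter are not given in the sources used here. Among all counted reads and summary lines of a library, reads without a unique alignment made up 28.83 to 40.29%, reads in no annotated feature 3.28 to 6.73%, and reads overlapping several features 0.46 to 0.65%. These lines were left out of library sizes and tests. Because reads aligning to several places enter no gene, genes with near-identical copies (here Gsta1, Ugt2b34, Ifitm3 and Hist1h2bc) carry uncertain counts. Y-linked genes with an X-linked partner may also lose reads shared with it. Without a stated strand setting, reads of overlapping genes on opposite strands, such as those within the Hoxd cluster, cannot be told apart.

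Symbols and coordinates came from GENCODE M21, which uses GRCm38, matched on the Ensembl identifier. Of 39179 genes in the tables, 37607 had a symbol. Gene totals per library ran from 5988447 to 18972176 counts (median 10485784), and 15352 to 17492 genes had at least 1 count. No 2 libraries of a group held identical values. The chi-square statistic per degree of freedom between replicates, over genes with at least 20 counts, lay between 2.04 and 19.43 in the pairs without clone19 replicate 3 and between 61.83 and 92.17 in its 4 pairs. All 20 libraries were kept, although spread above counting error does not show that they are separate cultures. Counting error sets a floor: 3 counts, the limit that a count of 0 allows, correspond to 0.158 to 0.501 CPM in single libraries, where CPM is the count relative to the library total on the customary scale. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

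The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr were tested (12671; 26508 were excluded for low counts), libraries were scaled by trimmed mean of M-values (TMM), and 1 quasi-likelihood model with a mean per group was fitted to all 20 libraries, so that the groups share 1 estimate of the spread. The common biological coefficient of variation was 9.02%. Each of 6 comparisons was tested with glmQLFTest, and genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Genes called over 2-fold passed glmTreat against a log2 bound of 1, which tests that the change exceeds 2-fold. Values given for a gene are CPM on TMM-scaled library sizes, as mean ± SD over 5 libraries, and fold changes are log2 with standard errors. For a gene with 0 counts in a group, the fold is a lower bound against 3 counts over that whole group. With 1 to 3 counts, the ratio of CPM is given with an exact 95% counting interval instead of the fitted value.

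Genes were called shared when over 2-fold in both clones with the same sign, and returned when such a gene was also changed in Rec against both clones in the opposite direction. Both clones were compared with the same 5 control libraries. The overlap was therefore computed again with the controls divided between the clones, and 20 simulations with unchanged groups against those controls were run.

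The 29 gene lists comprised epithelial, mesenchymal, miR-200 loci, NRF2 targets, HIF targets, glycolysis, TCA cycle, nuclear OXPHOS genes, the mitochondrial genome, heme synthesis and breakdown, urea cycle and arginine, amino acid response, 2-oxoglutarate dioxygenases of chromatin, DNA and H3K27 methyltransferases, cell cycle, p53 targets, interferon response, cholesterol synthesis, proximal tubule, distal tubule and collecting duct, nephron lineage factors, podocyte, endothelial, leukocyte, smooth muscle and pericyte, Hox genes, X and Y genes, replication histones, and the target Fh1. Of 679 listed members, 678 matched a gene in the tables. Lists with at least 3 tested members (26) were tested against all other genes with camera from limma 3.58.1, at a preset inter-gene correlation of 0.01, and adjusted by Benjamini-Hochberg within a comparison. Members called are counted over all genes tested, and counts adjusted over the list alone were equal unless both are given. Camera with an estimated correlation was run beside it, and both adjusted p-values are given for lists called at the preset. The lists were compiled from general knowledge and not from these samples. Some genes stand in several lists, and most glycolysis genes are also listed as HIF targets.

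The comparisons, lists, the tests used for them, most alternatives and the rule for naming genes were fixed before the data were examined. The tests named as such in the closing section were chosen later. The rule names 26 genes in all cases (Fh1, Cdh1, Epcam, Esrp1, Krt19, Vim, Fn1, Cdh2, Zeb1, Zeb2, Snai1, Snai2, Twist1, Twist2, Hmox1, Nqo1, Gclm, Slc7a11, Ass1, Asl, Slc2a1, Vegfa, Ldha, Tet1, Tet2 and Tet3). It adds the 8 higher and 8 lower shared genes whose smaller change of the 2 clones was largest, up to 2 further members per list, and the 6 higher and 6 lower returned genes. It also adds the 5 higher and 5 lower genes with the largest change between Rec and Fh1_fl_fl, and as many between the clones. Outside the fixed genes and lists, a gene needed a mean of at least 10 CPM in the higher group, an established name and no overlap between the libraries compared. A few genes that the rule selects are not reported here. Genes named outside this rule are Gm42418, Lars2, mt-Rnr1, mt-Rnr2, Gm47283 and the imprinted genes of the closing section, which were chosen after their values were seen.

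The pipeline was tested on simulated counts for 12671 genes, of which 12095 passed the filter. All 4 groups were drawn at the Fh1_fl_fl means and the real library sizes, with changes planted in the clones only. Nearly all simulated genes were thus unchanged, while 65.1 to 78.6% changed in the comparisons of the data. The simulation therefore does not test the scaling where most genes change. For clone1 against Fh1_fl_fl, edgeR recovered 76 of 100 genes changed 1.5-fold and 96 of 100 changed 4-fold. For clone19 against Fh1_fl_fl it recovered 77 and 96. Among the unchanged genes, 13 and 16 were called changed in these comparisons. Of the planted genes, 89 were called over 2-fold in both clones and returned, with 0 other genes. The same calls were repeated with median-ratio (RLE) scaling, with library totals alone, without the low-count filter, with a filter of 5 CPM in 5 libraries, with the replicate number as a block, with only the groups compared, with DESeq2 1.42.0, with an adjusted p under 0.01, with fry and an estimated correlation for the lists, and without each library in turn. An alternative without 4 genes that took a large share of 1 library, DESeq2 for named genes, the alternatives for differences between the clones, and the share undone with divided clone replicates were added after the data were seen.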

Results

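RNA sequencing counted the transcripts of 39179 annotated genes in immortalised kidney epithelial cells of C57BL/6J mice. Fh1 encodes fumarate hydratase, the TCA cycle enzyme that converts fumarate to malate. The series compares cells labelled by their Fh1 genotype in 4 groups of 5 libraries: Fh1_fl_fl cells (labelled Fh1 wild type), the clones clone1 and clone19 (labelled Fh1 deletion), and Rec cells (labelled Fh1 wild type re-expressed). The gene counts of the Fh1_fl_fl libraries, replicates 1 to 5, summed to 18972176, 8978370, 11541124, 13109985 and 12928763. Those of clone1 summed to 10451744, 10519824, 9211321, 6681589 and 12171975. The clone19 libraries had 5988447, 8803646, 6371298, 10095536 and 9687230 counts. Rec had 10805443, 10562475, 12400630, 8672778 and 17826881 counts. Gm42418, a locus that collects ribosomal RNA reads, took 8.202% of the counts of clone19 replicate 3 against a median of 0.3135% over all libraries. The first 3 principal components of the 12671 tested genes held 50.8%, 22% and 18.7% of the variance. The nearest other library belonged to the same group in 20 of 20 cases. The root-mean-square log2 distance between group means was 1.15 from Fh1_fl_fl to clone1, 0.97 to clone19 and 0.84 to Rec, 0.82 between the clones, 1.13 from clone1 to Rec and 0.97 from clone19 to Rec.

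The comparison of each clone with Fh1_fl_fl addressed how cells labelled Fh1 deletion differ in transcription from those labelled wild type. Fh1 itself (ENSMUSG00000026526; GRCm38 chromosome 1, 175600374 to 175625635, minus strand) was counted in all groups, at 92.4 ± 6.16 CPM in Fh1_fl_fl, 113 ± 5.94 in clone1, 84.8 ± 7.32 in clone19 and 71.3 ± 7.08 in Rec (mean ± SD, n = 5). The log2 fold change against Fh1_fl_fl was 0.29 in clone1 (SE 0.07, adjusted p = 0.000598), -0.12 in clone19 (SE 0.07, adjusted p = 0.124) and -0.37 in Rec (SE 0.07, adjusted p = 4.29e-05). Scaled to library totals, the clone1 difference was 0.15 (adjusted p = 0.0656) and the clone19 difference -0.25 (adjusted p = 0.00328), so neither outcome held under both scalings. Over all alternatives the adjusted p ran from 1.53e-05 to 0.0656 in clone1 and from 0.00328 to 0.36 in clone19. A whole-gene count includes exons outside any deleted part, so it does not measure the deletion, and Rec gave the lowest mean of the 4 groups.

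Cdh1 and Epcam fell in both clones, further in clone1. E-cadherin (Cdh1, ENSMUSG00000000303; chromosome 8, 106603351 to 106670246, plus strand), which joins neighbouring epithelial cells, went from 426 ± 55.6 CPM in Fh1_fl_fl to 168 ± 30.3 in clone1 and 272 ± 19.2 in clone19. Epcam (ENSMUSG00000045394; chromosome 17, 87635979 to 87651129, plus strand), an epithelial surface adhesion molecule, went from 439 ± 29.2 to 86.7 ± 13.8 and 226 ± 13.2 CPM. Esrp1 (ENSMUSG00000040728; chromosome 4, 11331933 to 11386783, minus strand), which directs epithelial splicing, had 171 ± 3.02 CPM in Fh1_fl_fl and 37.5 ± 1.89 in clone1, while clone19 had 166 ± 6.76. The tetraspan protein gene Mal2 went from 400 ± 21.5 to 2.22 ± 0.279 and 38.5 ± 5.87 CPM, and the tight junction gene Cldn3 from 143 ± 27.3 to 3.63 ± 0.915 and 14.8 ± 2.55. Krt19, an epithelial keratin, went the other way, from 348 ± 17.1 to 639 ± 71.2 and 458 ± 28.1 CPM. The log2 fold changes of Cdh1 were -1.34 in clone1 (SE 0.1, adjusted p = 1.28e-12) and -0.65 in clone19 (SE 0.1, adjusted p = 1.09e-06), and those of Epcam -2.34 (SE 0.08, adjusted p = 1.27e-19) and -0.96 (SE 0.08, adjusted p = 1.37e-11). For these 2 genes every library of both clones lay below every Fh1_fl_fl library. Esrp1 fell by 2.19 in clone1 (SE 0.05, adjusted p = 1.81e-22), and its difference in clone19 was -0.05 (SE 0.05, adjusted p = 0.428), or -0.17 when scaled to library totals (adjusted p = 0.0132, with 0.0132 to 0.681 over all alternatives). Of 41 tested members of the epithelial list, 36 fell and 4 rose in clone1 and 28 fell and 2 rose in clone19. Camera called the list lower in clone1 (adjusted p = 2.56e-20, or adjusted p = 0.00743 with an estimated correlation) and in clone19 (adjusted p = 1.65e-11, or adjusted p = 0.0523 with an estimated correlation). Its median log2 fold change was -1.61 in clone1 and -0.74 in clone19.

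Vim, Zeb1, Zeb2, Snai2 and Twist1 rose in both clones. Vimentin (Vim, ENSMUSG00000026728; chromosome 2, 13573927 to 13582826, plus strand), an intermediate filament of mesenchymal cells, went from 7.66 ± 1.01 CPM in Fh1_fl_fl to 567 ± 39.5 in clone1 and 69.5 ± 3.34 in clone19. Zeb1 (ENSMUSG00000024238; chromosome 18, 5591860 to 5775467, plus strand) and Zeb2 (ENSMUSG00000026872; chromosome 2, 44983632 to 45117395, minus strand) encode repressors of Cdh1. Zeb1 went from 3.26 ± 0.868 to 50.5 ± 6.7 and 17.6 ± 1.56 CPM, and Zeb2 from 2.82 ± 0.43 to 69.4 ± 7.58 and 50.5 ± 3.75. Snai2, a further such repressor, went from 0.819 ± 0.235 to 14.4 ± 0.837 and 8.18 ± 1.33 CPM, and Twist1 from 7.95 ± 0.735 to 15.2 ± 2.26 and 19.7 ± 1.16. Twist2 split the clones, at 5.93 ± 0.827 CPM in Fh1_fl_fl, 20.9 ± 2.71 in clone1 and 1.59 ± 0.397 in clone19. Fibronectin (Fn1) rose in clone19 alone, from 1560 ± 267 to 3750 ± 824 CPM (log2 fold change 1.27, adjusted p = 2.45e-08), with 1600 ± 365 in clone1 (0.04, adjusted p = 0.824), and differed between the clones by 1.23 (adjusted p = 6.11e-08). N-cadherin (Cdh2) fell in clone1, from 439 ± 48 to 205 ± 31.4 CPM (-1.1, adjusted p = 1.35e-11), with 416 ± 29.7 in clone19 (-0.08, adjusted p = 0.438). Scaled to library totals, Cdh2 in clone19 gave -0.20 (adjusted p = 0.0447, with 0.0447 to 0.804 over all alternatives). Vim rose by 6.22 in clone1 (SE 0.09, adjusted p = 1.54e-27) and 3.19 in clone19 (SE 0.08, adjusted p = 7.83e-22), Zeb1 by 3.95 and 2.42 (adjusted p = 1.77e-19 and 8.05e-14), and Zeb2 by 4.62 and 4.16 (adjusted p = 9.4e-22 and 3.21e-20). The matrix genes Tnc and Tgfbi went against this direction. Tnc fell from 21.3 ± 3.31 CPM to 3.27 ± 0.904 and 2.47 ± 0.747. Tgfbi fell from 7.83 ± 1.16 to 0.172 ± 0.174 CPM in clone1, and was lower by a ratio of 310 in clone19 (95% counting interval 55.7 to 12300). Snai1 (0.236 ± 0.177 CPM in Fh1_fl_fl, 0.262 ± 0.249 in clone1, 0.109 ± 0.159 in clone19 and 0.175 ± 0.193 in Rec) did not pass the count filter. Of 31 tested mesenchymal genes, 20 rose and 8 fell in clone1, and 20 rose and 9 fell in clone19. Camera called this list higher in clone1 (adjusted p = 0.00176, or 0.328 with an estimated correlation) and in clone19 (adjusted p = 0.00461, or 0.323 with an estimated correlation). The miR-200 loci, whose products repress Zeb1 and Zeb2, reached at most 0.09 CPM in any library, so 0 of 5 could be tested.

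**Figure D1:**
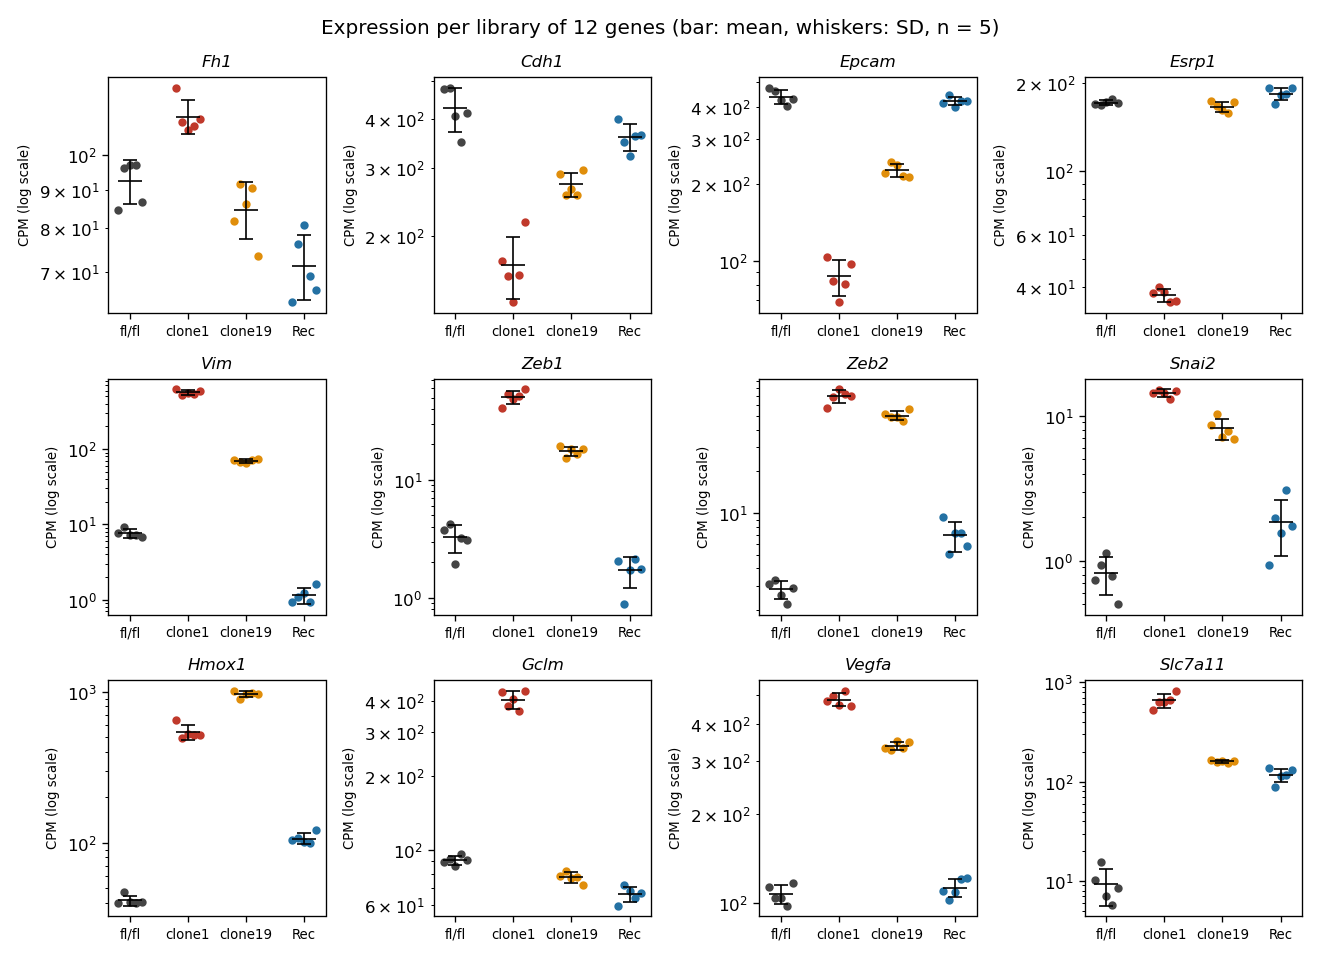
CPM of 12 genes in each of the 20 libraries, on a logarithmic axis, for Fh1_fl_fl, clone1, clone19 and Rec; the bar is the mean and the whiskers the SD of 5 libraries. Vim, Zeb1, Zeb2, Hmox1 and Vegfa lay higher and Epcam lower in both clones, while Gclm and Esrp1 separated clone1 from clone19.

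Antioxidant genes rose in both clones, more of them in clone1. Hmox1 (heme oxygenase 1, ENSMUSG00000005413; chromosome 8, 75093621 to 75100589, plus strand) went from 41.5 ± 3.13 CPM in Fh1_fl_fl to 541 ± 62 in clone1 and 965 ± 40.8 in clone19. The quinone reductase gene Nqo1 went from 2.92 ± 0.638 to 17.3 ± 1.3 and 13.5 ± 2.2 CPM, and the cystine importer gene Slc7a11 from 9.38 ± 3.74 to 657 ± 104 and 160 ± 4.62. Gclm, a subunit of the enzyme that starts glutathione synthesis, rose in clone1 only, from 91.1 ± 3.89 to 406 ± 33 CPM, with 77.5 ± 3.73 in clone19. Gsta1, a glutathione transferase with near-identical copies whose counts are uncertain for that reason, went from 0.392 ± 0.309 to 169 ± 14.5 and 11.6 ± 3.65 CPM. The aldehyde dehydrogenase gene Aldh3a1 was higher by a ratio of 3560 in clone1 (639 to 141000) and 27.8 in clone19 (5 to 1100). Hmox1 rose by 3.71 in clone1 (SE 0.08, adjusted p = 5.54e-24) and 4.54 in clone19 (SE 0.08, adjusted p = 4.67e-25). Gclm rose by 2.16 in clone1 (SE 0.06, adjusted p = 3.21e-21) and fell by 0.23 in clone19 (SE 0.06, adjusted p = 0.00186). Among 37 tested NRF2 targets, 33 rose and 3 fell in clone1 (34 and 3 adjusted over the list alone), and 23 rose and 10 fell in clone19. Camera gave an adjusted p of 3.05e-28 in clone1 (adjusted p = 0.0038 with an estimated correlation) and of 4.44e-06 in clone19 (adjusted p = 0.152 with an estimated correlation).

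Hypoxia-inducible and glycolytic genes rose in both clones. Vegfa (ENSMUSG00000023951; chromosome 17, 46016993 to 46032369, minus strand), an angiogenic growth factor and HIF target, went from 107 ± 7.65 CPM in Fh1_fl_fl to 484 ± 24.1 in clone1 and 338 ± 10.3 in clone19. The glucose transporter gene Slc2a1 went from 95.3 ± 10.4 to 365 ± 57 and 232 ± 22.7 CPM, and the lactate dehydrogenase gene Ldha from 1180 ± 88.1 to 2370 ± 247 and 2160 ± 80.8. Ero1l, an oxidase of the endoplasmic reticulum, went from 54.1 ± 3.49 to 892 ± 85.8 and 787 ± 62.7 CPM, and the carbonic anhydrase gene Car12 from 9.23 ± 1.17 to 114 ± 12.2 and 71.1 ± 2.7. The glycolytic genes Pfkp (16.7 ± 1.43 to 105 ± 3.02 and 145 ± 7.59 CPM) and Eno2 (5.66 ± 1.7 to 47.4 ± 7.02 and 42.3 ± 3.09) did likewise. Vegfa rose by 2.17 (SE 0.06, adjusted p = 1.07e-21) and 1.66 (SE 0.06, adjusted p = 6.9e-19), Slc2a1 by 1.94 and 1.28 (adjusted p = 1.84e-16 and 1.81e-12), and Ldha by 1.01 and 0.88 (adjusted p = 2.17e-13 and 5.99e-12). For these 7 genes every library of both clones lay above every Fh1_fl_fl library. Of 37 tested HIF targets, 35 rose and 2 fell in clone1, and 34 rose and 1 fell in clone19 (34 and 2 adjusted over the list alone). Camera gave adjusted p = 1.33e-21 and 7.76e-20, or 0.00197 and 0.0013 with an estimated correlation. All 19 tested glycolysis genes rose in clone1 and 18 of them in clone19, with 0 lower at an adjusted p under 0.05 by edgeR. For that list camera gave adjusted p = 2.28e-14 and 1.66e-10, or 0.0111 and 0.0399 with an estimated correlation. Most listed glycolysis genes, among them Pfkp, Ldha and Slc2a1, are also listed HIF targets, so the lists are not separate evidence.

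The amino acid response was also higher in both clones. Ddit3 (ENSMUSG00000025408; chromosome 10, 127290774 to 127296288, plus strand), a transcription factor of the integrated stress response, went from 13.7 ± 1.14 CPM in Fh1_fl_fl to 342 ± 23.1 in clone1 and 206 ± 14.4 in clone19. The pseudokinase gene Trib3 went from 17.2 ± 3.98 to 201 ± 19.2 and 143 ± 5.93 CPM. Of 29 list members, 27 rose and 1 fell in clone1, and 26 rose and 2 fell in clone19 (camera adjusted p = 7.92e-16 and 5.54e-21, or 0.0303 and 0.0163 with an estimated correlation). 2 genes of argininosuccinate metabolism moved in opposite directions. Ass1, which makes argininosuccinate, went from 10.1 ± 1.02 to 15.4 ± 0.66 and 83.4 ± 4.28 CPM (log2 fold changes 0.61 and 3.05, adjusted p = 7.46e-07 and 1.38e-21). Asl, which splits it into arginine and fumarate, fell from 53.4 ± 2.57 to 24.7 ± 3.09 and 33.9 ± 2.85 CPM (-1.1 and -0.65, adjusted p = 3.54e-13 and 1.33e-08). Arg2 fell from 27 ± 3.23 to 2.96 ± 0.698 and 13.7 ± 3.02 CPM, and Odc1, which starts polyamine synthesis, rose from 97.4 ± 4.15 to 187 ± 14.2 and 195 ± 10.1. The urea cycle and arginine list as a whole was not called (6 higher and 2 lower of 9 in clone1, 4 and 4 in clone19; camera adjusted p = 0.0917 and 0.175). In the TCA cycle list, pyruvate carboxylase (Pcx) went from 23.9 ± 1.95 to 77.8 ± 10.9 and 74.6 ± 10.5 CPM and the succinate dehydrogenase subunit Sdha from 155 ± 4.9 to 420 ± 25.4 and 257 ± 15.4. Of 25 tested members 19 rose and 2 fell in clone1 (camera adjusted p = 0.00247, or 0.332 with an estimated correlation), and 12 rose and 4 fell in clone19 (adjusted p = 0.184).

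Across all genes, 9954 of 12671 (78.6%) changed in clone1 and 9241 (72.9%) in clone19. In clone1 4820 were higher and 5134 lower, and in clone19 4664 and 4577. Scaled to library totals, the share of changed genes that were higher went from 48.42 to 40.1% in clone1 and from 50.47 to 40.68% in clone19. With RLE scaling it was 50.34% in clone1, and over all alternatives it reached 51.11% there and 51.39% in clone19, so neither direction held a stable majority. Over 2-fold changes were called for 2752 genes in clone1 (1377 higher, 1375 lower) and 1961 in clone19 (1039 higher, 922 lower). The median absolute log2 fold change was 0.58 and 0.48. Both clones shared 694 genes over 2-fold higher and 641 lower, 1335 in all, against 112.9 and 100.1 for independent lists, while 32 and 13 genes went over 2-fold in opposite directions. With the control libraries divided between the clones the overlap was 1255. Dividing them removes shared sampling noise only, so a feature particular to the Fh1_fl_fl cells would still count as shared by the clones. The shared lower genes included 4 Y-linked genes, and 436 shared genes stayed over 2-fold from Fh1_fl_fl on the same side in Rec. The overlap therefore does not measure an effect of the Fh1 label alone. 20 simulations of unchanged groups against shared controls gave 0, which edgeR's 2-fold bound fixes for unchanged genes, so this count does not test the overlap. Over the tested genes, which are not independent replicates, the log2 fold changes of the clones correlated at 0.7239 with shared controls and at 0.6987 with divided controls, and unchanged simulated groups gave 0.4572. The covariance was 1.511 with shared and 1.609 with divided controls, and 0.008275 in the simulated groups. Among shared genes with higher counts, the betaine transporter gene Slc6a12 went from 0.46 ± 0.15 CPM to 49.8 ± 5.6 in clone1 and 147 ± 9.37 in clone19. The corneodesmosin gene Cdsn went from 0.071 ± 0.0417 to 19.5 ± 3.24 and 18.4 ± 3.14 CPM, and the collagen receptor gene Ddr2 from 0.523 ± 0.245 to 34 ± 4.68 and 97.1 ± 8.95. Igfbp4, which binds insulin-like growth factors, reached 277 ± 38.7 and 17.3 ± 2.34 CPM from 0.168 ± 0.157. The basement membrane collagen gene Col4a1 reached 16 ± 3.55 and 34.5 ± 6.61 CPM from 0.427 ± 0.144, and its neighbour Col4a2 12.8 ± 2.49 and 14.3 ± 4.25 from 0.386 ± 0.15. Trim54 reached 46.4 ± 3.8 and 11.9 ± 1.81 CPM from 0.221 ± 0.156, and Ugt2b34, a glucuronosyltransferase of a family with close copies and so an uncertain count, 621 ± 84.8 and 16 ± 1.53 from 0.255 ± 0.191. Among shared genes with lower counts, the kidney development factor Lhx1 had 25.9 ± 1.34 CPM in Fh1_fl_fl and was lower by ratios of 618 in clone1 (171 to 5100) and 525 in clone19 (145 to 4330). The mechanosensitive channel gene Piezo2 went from 35.4 ± 4.18 to 0.0801 ± 0.127 and 0.148 ± 0.205 CPM, and Lypd6b from 16.7 ± 1.51 by a ratio of 402 in clone1 (111 to 3320) and to 0.105 ± 0.177 CPM in clone19. Bik, a pro-apoptotic gene, went from 13.3 ± 0.758 to 0.121 ± 0.138 CPM in clone1 and was lower by a ratio of 180 in clone19 (61.4 to 871).

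4 Y-linked genes were detected in Fh1_fl_fl and nearly absent elsewhere. Ddx3y (chromosome Y, 1260771 to 1286629), an RNA helicase gene, had 17.4 ± 1.29 CPM in Fh1_fl_fl and was at least 273-fold lower in clone1, 231-fold in clone19 and 338-fold in Rec. Eif2s3y (1010543 to 1028847), a translation factor gene, had 30.7 ± 1.76 CPM and was lower by a ratio of 1450 in clone1 (260 to 57300), and at least 411-fold in clone19 and 599-fold in Rec. For the histone demethylase gene Kdm5d (897788 to 956786), with 14.1 ± 1.61 CPM, the difference was at least 220-fold in clone1 and 272-fold in Rec, and 1 count was seen in clone19. Its relative Uty (1096861 to 1245759), with 14.9 ± 1.24 CPM, gave ratios of 716 (128 to 28300), 304 (84.1 to 2510) and 886 (159 to 35000). These 4 tested members made up the X and Y list, which camera called lower in clone1, clone19 and Rec (adjusted p = 2.55e-08, 1.35e-10 and 4.24e-15, or 0.0111, 0.0143 and 0.00226 with an estimated correlation).

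Single kidney identity and chromatin genes changed in both clones, including members of lists that were not called. Hox genes, which set position along the body axis, fell in 24 of 31 and rose in 2 in clone1, and fell in 25 and rose in 5 in clone19 (camera adjusted p = 0.00176 and 0.000126, or 0.0953 and 0.0523 with an estimated correlation). Hoxd11 had 8.74 ± 0.561 CPM in Fh1_fl_fl, was lower by a ratio of 209 in clone1 (57.8 to 1720), and had 0.137 ± 0.084 CPM in clone19. Hoxd13 went from 3.64 ± 0.146 to 0.169 ± 0.169 CPM in clone1 and was lower by a ratio of 148 in clone19 (26.5 to 5840). The nephron factor Pax2 fell from 272 ± 20.4 to 45.4 ± 4.52 and 42 ± 8.98 CPM, although its list was not called in the clones (6 higher and 5 lower of 13, and 6 and 6; camera adjusted p = 0.834 and 0.161). Cholesterol synthesis genes were lower in clone19 (18 fell and 2 rose of 24; camera adjusted p = 0.000517, or 0.323 with an estimated correlation). In clone1 the list was not called (11 fell and 7 rose; adjusted p = 0.659). The isoprenoid enzyme gene Idi1 fell from 185 ± 13.7 CPM to 87.8 ± 5.96 in clone1 and 63.5 ± 8.66 in clone19. Heme metabolism was called higher in clone19 (6 higher and 6 lower of 14, 7 and 6 adjusted over the list alone; adjusted p = 0.0385), but not with an estimated correlation (0.323), without the count filter (0.376) or without Fh1_fl_fl replicate 4 (0.0509), in a range of 0.0267 to 0.376 over camera's alternatives. In clone1 it was not called (7 and 5, adjusted p = 0.135). Its biliverdin reductase gene Blvrb rose from 3.79 ± 0.577 to 42 ± 3.91 and 18.6 ± 2.44 CPM, and Uros fell from 10.8 ± 1.47 to 2.28 ± 1.05 and 2.97 ± 0.437. Tet2, a 2-oxoglutarate-dependent DNA dioxygenase, fell from 6.24 ± 0.865 to 4.64 ± 0.9 and 0.352 ± 0.161 CPM (-0.47 and -4.14, adjusted p = 0.0043 and 2.96e-14), and Tet3 from 52.4 ± 3.35 to 38.5 ± 6.06 and 24.4 ± 2.78. Tet1 had 0.15 ± 0.125 CPM in Fh1_fl_fl, 0.273 ± 0.156 in clone1, 0.125 ± 0.228 in clone19 and 0.552 ± 0.262 in Rec, under the filter. Of the same enzyme class, the demethylase genes Alkbh5 and Phf8 rose, Alkbh5 from 199 ± 9.69 to 538 ± 39 and 343 ± 20.2 CPM and Phf8 from 4.31 ± 0.711 to 7.81 ± 1.6 and 8.43 ± 1.16. The 2-oxoglutarate dioxygenase list was not called (8 rose and 4 fell of 18 in clone1, 9 and 4 in clone19; adjusted p = 0.286 and 0.946). The DNA and H3K27 methyltransferases were not called either (4 rose and 3 fell of 8, and 4 and 2; adjusted p = 0.871 and 0.946). Among them, Dnmt3b fell from 5.04 ± 0.561 to 0.92 ± 0.467 and 0.301 ± 0.161 CPM, and Eed rose from 43.8 ± 3.62 to 71.8 ± 3.18 and 64.1 ± 8.14.

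Nuclear OXPHOS genes rose more often than they fell without being called by camera (41 and 10 of 76 in clone1, 35 and 7 in clone19, or 33 and 6 adjusted over the list alone; adjusted p = 0.135 and 0.284). Without the count filter camera called this list higher in clone1 (adjusted p = 0.00269, in a range of 0.00269 to 0.904 over camera's alternatives). The complex III subunit Uqcrq went from 52.5 ± 5.59 to 96.1 ± 4.93 and 89.5 ± 8.29 CPM. Mitochondrially encoded transcripts moved apart. Those of mt-Co1 rose from 7040 ± 780 to 21100 ± 1970 and 15600 ± 1870 CPM, and those of mt-Nd1 fell from 2750 ± 366 to 1250 ± 161 and 1550 ± 251. Of the 12 genes, 1 rose and 9 fell in clone1, and 5 rose and 4 fell in clone19 (camera adjusted p = 0.261 and 0.946). Without the count filter the list was called lower in clone1 (0.0454, in a range of 0.0454 to 0.87 over camera's alternatives). Proliferation genes went both ways, with 17 higher and 12 lower of 36 in clone1 and 20 and 10 in clone19 (adjusted p = 0.871 and 0.38). The nucleotide synthesis genes Rrm2 (148 ± 9.43 to 47 ± 4.43 and 73.5 ± 4.5 CPM) and Tyms (82.4 ± 4.83 to 28.4 ± 1.37 and 32.7 ± 3.41) fell. Among p53 targets, 8 rose and 8 fell of 20 in clone1, and 11 rose and 4 fell in clone19 (adjusted p = 0.957 and 0.542). The death receptor gene Fas rose from 0.16 ± 0.149 to 2.69 ± 0.689 and 2.25 ± 0.73 CPM, and Trp53inp1 fell from 83.6 ± 5.08 to 33.4 ± 5.46 and 22.6 ± 2.11. Interferon response genes fell in 10 and rose in 4 of 16 in clone1, and fell in 8 and rose in 3 in clone19 (adjusted p = 0.331 and 0.38). Parp14 fell from 19.7 ± 1.29 to 2.38 ± 0.654 and 4.55 ± 0.676 CPM, and Ifitm3, whose close copies make its count uncertain, from 10.4 ± 1.37 to 0.982 ± 0.222 and 3.04 ± 1.12. The remaining cell type lists had few tested members and were not called by camera in either clone. Proximal tubule genes rose in 3 and fell in 1 of 5 in clone1, and in 4 and 1 in clone19 (adjusted p = 0.141 and 0.902). Distal tubule and collecting duct genes rose in 2 and fell in 2 of 5, and in 3 and 2 (adjusted p = 0.419 and 0.542). In both clones 1 podocyte gene rose and 3 fell of 4 (adjusted p = 0.261 and 0.357). Endothelial genes rose in 4 and fell in 0 of 4 in clone1, and in 1 and 1 in clone19 (adjusted p = 0.233 and 0.532). Leukocyte genes rose in 1 and fell in 1 of 3, and in 1 and 2 (adjusted p = 0.659 and 0.263). Smooth muscle and pericyte genes rose in 2 and fell in 2 of 4, and in 4 and 0 (adjusted p = 0.957 and 0.172). Umod, a thick ascending limb gene kept in the proximal tubule list, had 3.16 ± 0.468 CPM in Fh1_fl_fl and was at least 49.9-fold lower in clone1, 42.3-fold in clone19 and 61.8-fold in Rec. The brush border peptidase gene Anpep rose from 0.0864 ± 0.0907 to 5.41 ± 0.638 and 0.716 ± 0.0969 CPM. The water channel gene Aqp3 went from 1.15 ± 0.367 to 0.214 ± 0.278 and 0.352 ± 0.481 CPM, Gata3 from 4.88 ± 0.216 to 27.4 ± 2.56 and 12.5 ± 1.21, and Podxl from 126 ± 10.2 to 212 ± 35 and 200 ± 15.6. Cdkn1c, a cell cycle inhibitor, had 10.2 ± 0.606 CPM in Fh1_fl_fl, was lower by a ratio of 485 in clone1 (87 to 19100), and had 2.11 ± 0.58 CPM in clone19. The endothelial cadherin gene Cdh5 went from 0.121 ± 0.0754 to 1.7 ± 0.644 and 7.92 ± 0.918 CPM, Csf1r from 43.5 ± 2.63 to 13.3 ± 1.47 and 7.54 ± 2.17, and Cd68 from 3.97 ± 0.468 to 7.61 ± 0.998 and 18.1 ± 1.27. Desmin (Des) was higher by ratios of 222 (61.3 to 1830) and 79.2 (21.9 to 654), and Lmod1, at 0 counts in Fh1_fl_fl, was at least 5.42-fold and 34.8-fold higher. The signs of median, mean and camera's direction differed for some lists that were not called, in clone1 for DNA and H3K27 methyltransferases, cell cycle and p53 targets. In clone19 they differed for both chromatin lists, proximal tubule and endothelial genes. Of the replication histones only Hist1h2bc was tested, a member of a family with near-identical copies and so uncertain, at 4.87 ± 0.54 CPM in Fh1_fl_fl, 6.21 ± 0.864 in clone1, 20.7 ± 3.32 in clone19 and 6.28 ± 0.423 in Rec.

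The comparison of Rec with each clone addressed which changes of the clones are absent from cells labelled Fh1 re-expressed. Re-expression is not seen in the whole-gene Fh1 counts, which were lower in Rec than in clone1 and clone19 (-0.66 and -0.25, adjusted p = 3.49e-09 and 0.0032). Vim dropped to 1.16 ± 0.284 CPM in Rec, Zeb1 to 1.7 ± 0.492, Zeb2 to 6.94 ± 1.66 and Snai2 to 1.85 ± 0.777, while Cdh1 had 360 ± 28.7, Epcam 422 ± 15.9, Esrp1 183 ± 9.15 and Cldn3 48.3 ± 5.51. Hmox1 dropped to 107 ± 8.51 CPM, Nqo1 to 3.1 ± 0.789, Gclm to 66.2 ± 4.78 and Vegfa to 113 ± 8.14, and Slc2a1 (86.2 ± 5.93), Ldha (1080 ± 58.2), Pfkp (16 ± 2) and Eno2 (1.42 ± 0.552) dropped with them. Mal2 (38.8 ± 2.07 CPM) was above clone1 but was not called against clone19 (log2 fold change 0.01, adjusted p = 0.893), and Twist1 (17.6 ± 2.01) was not called against either clone (0.2 and -0.16, adjusted p = 0.073 and 0.145), though without clone1 replicate 1 it was called above clone1 (0.0389, in a range of 0.0389 to 0.275). Slc7a11 came to 117 ± 18.3 CPM. Against clone1 and clone19, Vim fell by 8.85 and 5.83 (SE 0.11 and 0.11; adjusted p = 6.85e-29 and 4.81e-24), Hmox1 by 2.34 and 3.18 (adjusted p = 1.5e-20 and 1.07e-22), and Epcam rose by 2.28 and 0.9 (adjusted p = 2.28e-19 and 4.47e-11). For these 3 genes no Rec library overlapped a clone library. Rec differed from clone1 in 9865 genes (5033 higher, 4832 lower; 2787 over 2-fold, 1156 higher and 1631 lower) and from clone19 in 9355 (4540 higher, 4815 lower; 1960 over 2-fold, 648 higher and 1312 lower). Camera called the epithelial list higher, with 34 genes up and 4 down against clone1 and 26 and 7 against clone19 (adjusted p = 1.4e-15 and 9.74e-07, or 0.0123 and 0.158 with an estimated correlation). The mesenchymal list was lower, with 6 up and 19 down, and 5 and 20, or 5 and 21 adjusted over the list alone (camera adjusted p = 5.8e-06 and 2.36e-06, or 0.223 and 0.151 with an estimated correlation). NRF2 targets were lower, with 4 up and 33 down, and 5 and 27, or 6 and 27 adjusted over the list alone (camera adjusted p = 5.01e-27 and 2.52e-05, or 0.00369 and 0.159 with an estimated correlation). So were HIF targets, with 1 up and 35 down, and 2 and 34 (camera adjusted p = 2.93e-24 and 1.65e-22, or 0.0019 and 0.00107 with an estimated correlation). Glycolysis was lower, with 1 up and 18 down, and 1 and 17 (camera adjusted p = 2.01e-15 and 1.6e-11, or 0.0123 and 0.0428 with an estimated correlation). The cell cycle list was higher, with 34 up and 1 down, and 31 and 3 (camera adjusted p = 6.56e-12 and 4.49e-12, or 0.0123 and 0.0175 with an estimated correlation). Against clone19, cholesterol synthesis was higher, with 20 up and 1 down (camera adjusted p = 1.81e-06, or 0.151 with an estimated correlation) and Idi1 at 332 ± 35.8 CPM. Smooth muscle genes were lower than in clone19, with 0 up by edgeR and 4 down of 4 (camera adjusted p = 0.0137, or 0.151 with an estimated correlation). Against clone1, the chromatin dioxygenases were lower, with 1 up and 13 down (camera adjusted p = 0.0124, or 0.586 with an estimated correlation). The proximal tubule list was lower than in clone1 as well, with 1 up and 3 down (camera adjusted p = 0.0192), but not with the replicate number as a block (0.0819), with an estimated correlation (0.223) or without the count filter (0.316, in a range of 0.00564 to 0.316 over camera's alternatives).

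Of the 1335 genes shared by the clones, 999 (74.8%) returned in Rec, 597 of those higher in the clones (86%) and 402 of those lower (62.7%). Returned asks only for a change against both clones, so a returned gene may lie short of the Fh1_fl_fl level or beyond it. With shared genes chosen on clone replicates 1 to 3 and compared with Rec on replicates 4 and 5, 884 of 1277 returned (69.2%), 82.4% of those higher and 54.7% of those lower. By list, the genes that returned were 17 of 17 HIF targets higher in both clones, 8 of 8 glycolysis genes, 8 of 8 mesenchymal genes, 14 of 15 NRF2 targets and 6 of 13 amino acid response genes. On the lower side they were 7 of 9 epithelial, 4 of 6 Hox and 1 of 3 mesenchymal genes, and 0 of 4 Y-linked genes. Lists share members, as HIF targets and glycolysis do, so a gene can enter several of these counts. In 51 shared genes Rec changed against both clones in the direction away from Fh1_fl_fl. The median share of the log2 difference that was undone was 74.7% for genes higher and 52.6% for genes lower in the clones (73.2 and 50.9% with the replicates divided in that way), and 436 shared genes stayed over 2-fold from Fh1_fl_fl on the same side in Rec. Rec was called different from Fh1_fl_fl in 464 of the 694 shared genes higher in the clones and 570 of the 641 lower. In Rec, 27 and 6 of these shared genes lay over 2-fold beyond Fh1_fl_fl on the opposite side. Among returned genes that went up, the leptin receptor gene Lepr had 20.4 ± 1.58 CPM in Fh1_fl_fl, 1.78 ± 0.407 and 0.46 ± 0.4 in the clones and 56.5 ± 5.43 in Rec. Tmprss11e had 7.96 ± 0.396, 0.122 ± 0.143, 2.03 ± 0.411 and 34.8 ± 4.72 CPM in that order, and the transcription factor gene Myb 1.67 ± 0.291, 0.175 ± 0.155, 0.396 ± 0.181 and 10.1 ± 0.574. Slfn9 (13.9 ± 1.1 CPM in Fh1_fl_fl), Vsnl1 (20.5 ± 1.36) and Moxd1 (14 ± 1.6) came to 14.5 ± 1.66, 15.4 ± 1.42 and 10.5 ± 0.942 in Rec from 0.778 ± 0.206, 0.922 ± 0.338 and 0.479 ± 0.22 in clone1. On the way down, the imprinted gene Peg3 (ENSMUSG00000002265; chromosome 7, 6703892 to 6730431, minus strand) had 146 ± 7.37 CPM in Fh1_fl_fl, 1020 ± 310 in clone1, 874 ± 54.1 in clone19 and 0.113 ± 0.0363 in Rec. The ectonucleotidase gene Nt5e, with 20.6 ± 1.86 and 44.6 ± 2.44 CPM in the clones, was at 0 counts in Rec, at least 404-fold and 878-fold lower. Armcx2 (26.5 ± 2.51 and 14.3 ± 1.49 CPM in the clones) and Elmo1 (15.1 ± 2.59 and 11.3 ± 1.57) came to 0.136 ± 0.101 and 0.129 ± 0.0969 in Rec, Ugt2b34 to 0.0827 ± 0.0599 and Col4a2 to 0.0702 ± 0.105. Peg3, Nt5e and Armcx2 ended below Fh1_fl_fl, and Lepr, Tmprss11e and Myb above it.

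Rec and Fh1_fl_fl were compared to ask how far cells labelled Fh1 wild type re-expressed resemble those labelled Fh1 wild type. Rec stayed above Fh1_fl_fl in Hmox1, Slc7a11, Ddit3 and Trib3, and below it in Gclm (-0.46, adjusted p = 3.24e-07). The log2 fold change was 1.37 for Hmox1 (SE 0.07, adjusted p = 5.12e-15), 3.67 for Slc7a11 (SE 0.16, adjusted p = 6.45e-17), 1.46 for Ddit3 (37.6 ± 3.77 CPM in Rec; adjusted p = 6.9e-15) and 2.11 for Trib3 (73.7 ± 1.82 CPM; adjusted p = 1.28e-16). All Rec libraries of these 4 genes lay above all Fh1_fl_fl libraries. Rrm2 and Odc1 were higher, with Rrm2 at 572 ± 17.1 CPM (log2 fold change 1.95, adjusted p = 7.66e-20) and Odc1 at 656 ± 26.9 (2.75, adjusted p = 2.6e-23). Vim lay lower (-2.63, adjusted p = 3.26e-15) and Zeb2 and Twist1 higher (1.29 and 1.15, adjusted p = 4.22e-08 and 2.68e-10). Krt19 (682 ± 53.8 CPM) was higher too, while Ass1 (4.98 ± 0.808), Asl (34.1 ± 1.51), Tet2 (2.17 ± 0.196), Tet3 (42.2 ± 3.96), Pax2 (96 ± 4.14) and Lhx1 (1.98 ± 0.339) were lower. No difference was called for Epcam (-0.06, adjusted p = 0.504), Esrp1 (0.1, adjusted p = 0.076), Vegfa (0.07, adjusted p = 0.28) or Nqo1 (0.1, adjusted p = 0.648). The same held for Slc2a1 (-0.15, adjusted p = 0.161), Ldha (-0.13, adjusted p = 0.0939) and Fn1 (1520 ± 258 CPM; -0.03, adjusted p = 0.848). Scaled to library totals, Epcam, Slc2a1 and Ldha were called lower (-0.19, -0.28 and -0.26, adjusted p = 0.0208, 0.00956 and 0.00135), and these were their lowest values, with up to 0.876, 0.471 and 0.316 under other alternatives. Ldha was also called lower without Fh1_fl_fl replicate 2 (0.0337). Cdh1 was called lower (-0.24, adjusted p = 0.0243), but not without Fh1_fl_fl replicate 1 (0.096) or 2 (0.0807) or Rec replicate 2 (0.0678), 3 (0.074) or 4 (0.053), in a range of 0.000922 to 0.096. Esrp1 was called higher with DESeq2 (0.0316), with only the groups compared (0.0401), without Gm42418, Lars2, mt-Rnr1 and mt-Rnr2 (0.0449) and without Rec replicate 2 (0.0135), in a range of 0.0135 to 0.65. In all, 8966 genes (70.8%) differed, 4228 higher and 4738 lower, with 1401 over 2-fold (458 higher, 943 lower) and a median absolute log2 fold change of 0.44. The share of changed genes that were higher was 47.16%, and 36.55% when scaled to library totals. That scaling moved the median log2 fold change of all tested genes by -0.132 in Rec, -0.142 in clone1 and -0.124 in clone19 against Fh1_fl_fl. Camera called the cell cycle list higher, with 34 up and 1 down (adjusted p = 3.84e-19, or 0.00226 with an estimated correlation). The amino acid response was higher too, with 24 up and 4 down, or 25 and 4 adjusted over the list alone (camera adjusted p = 5.82e-17, or 0.0255 with an estimated correlation). Interferon response genes were lower, with 1 up and 13 down, Ifitm3 falling to 0.383 ± 0.27 CPM (camera adjusted p = 0.000967, or 0.0132 with an estimated correlation). Hox genes were lower, with 3 up and 25 down (camera adjusted p = 0.000967, or 0.0598 with an estimated correlation), as were nephron lineage factors, with 0 up by edgeR and 8 down of 13 (camera adjusted p = 0.000975, or 0.0598 with an estimated correlation). Podocyte genes were lower, with 1 up and 3 down (camera adjusted p = 0.00412, or 0.0334 with an estimated correlation), but not without the count filter (0.15, in a range of 0.0013 to 0.15 over camera's alternatives). HIF targets (11 up, 15 down), NRF2 targets (15 and 15) and glycolysis genes (6 and 5, or 5 and 5 adjusted over the list alone) were not called, with camera adjusted p = 0.558, 0.612 and 0.612. Neither were epithelial (8 up, 18 down) and mesenchymal genes (11 and 14), with adjusted p = 0.083 and 0.0781. The mesenchymal list was called without Fh1_fl_fl replicate 4 (0.0339, in a range of 0.0339 to 0.603 over camera's alternatives). For glycolysis the median log2 fold change was 0.01 and the mean -0.23, and camera's direction was down. Among single genes, the ion channel family gene Ano3 (11 ± 1.67 CPM in Rec) was higher by a ratio of 787 (141 to 31100). The muscle gene Xirp2 (23.8 ± 3.86 CPM), the receptor gene P2ry12 (13.9 ± 1.23) and Mctp1 (10.4 ± 1.9) rose by 7.93, 5.03 and 5.35 on the log2 scale. Mest, Grb10, Gnai1 and Zfp334, at 25.8 ± 2.06, 22.1 ± 2.47, 21.5 ± 1.91 and 20.1 ± 1.3 CPM in Fh1_fl_fl, were at 0 counts in Rec, at least 509, 430, 418 and 399-fold lower.

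**Figure D2:**
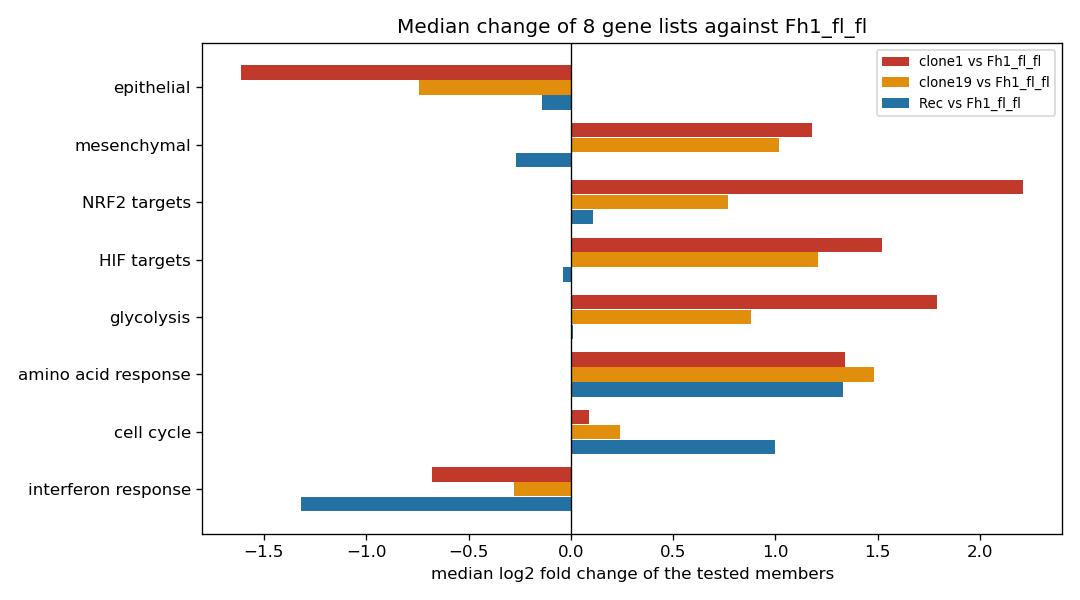
Median log2 fold change against Fh1_fl_fl over the tested members of 8 gene lists, as bars from 0, for clone1 (red), clone19 (orange) and Rec (blue). HIF targets had medians of 1.52 and 1.21 in the clones and -0.04 in Rec, and the amino acid response 1.34, 1.48 and 1.33. Most listed glycolysis genes are also listed HIF targets.

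The comparison of clone19 with clone1 measured how far 2 clones with the same label differ. Esrp1 was higher in clone19 by 2.14 (SE 0.06, adjusted p = 1.97e-21) and Mal2 by 4.09 (SE 0.12, adjusted p = 2.03e-20), while Vim was lower by -3.03 (SE 0.07, adjusted p = 3.31e-22) and Gclm by -2.39 (SE 0.06, adjusted p = 5.27e-21). Arginase 1 (Arg1), which splits arginine to urea and ornithine, had 79.6 ± 3.34 CPM in clone1 and 0.391 ± 0.125 in clone19, against 3.41 ± 0.531 in Fh1_fl_fl (clone19 against clone1, -7.7, adjusted p = 3.31e-22). Ass1 went the other way (2.44, adjusted p = 1.92e-19). The ubiquitin ligase gene Trim50 (29.3 ± 3.99 CPM in clone19), the homeobox-like gene Hopx (14.5 ± 1.64) and the vesicle gene Sytl4 (15.6 ± 1.77) had 0 counts in clone1. They were at least 464, 228 and 246-fold higher in clone19. Tspan6 (40.2 ± 8.09 CPM) and Fam169b (10.9 ± 1.87) were higher by ratios of 636 (217 to 3080) and 505 (90.7 to 20000). In the other direction, the mucin gene Muc5b (28.1 ± 10.6 CPM in clone1), R3hdml (38.7 ± 2.57) and Armcx3 (27 ± 3.31) gave ratios of 580 (160 to 4790), 526 (180 to 2550) and 535 (148 to 4420), and Aldh3a1 fell by 6.95. Between the clones 8247 genes (65.1%) differed, 4241 higher and 4006 lower in clone19, and 1214 were over 2-fold, 607 each way. Camera called the epithelial list higher in clone19 (31 rose, 6 fell; adjusted p = 8.81e-08, or 0.325 with an estimated correlation). NRF2 targets were lower in clone19, with 3 up and 34 down (camera adjusted p = 4.67e-28, or 0.00576 with an estimated correlation). HIF targets were lower, with 7 up and 24 down, or 8 and 25 adjusted over the list alone (camera adjusted p = 0.00536, or 0.504 with an estimated correlation). Glycolysis was lower, with 3 up and 12 down, or 4 and 12 adjusted over the list alone (camera adjusted p = 0.00153, or 0.504 with an estimated correlation). The TCA cycle (4 up, 15 down; camera adjusted p = 0.0166, or 0.572 with an estimated correlation) and cholesterol synthesis (4 up, 17 down, or 5 and 17 adjusted over the list alone; 0.00197, or 0.504 with an estimated correlation) were lower too.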

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

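The tests chosen after the result was seen were the 3 tests of the Y-linked genes, the nearest-library and whole-gene count tests of Fh1, and the shuffling of chromosome labels.

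37 of the named genes differed by over 2-fold between the clones in edgeR's glmTreat test of clone19 against clone1, 18 higher and 19 lower in clone19, so their change against Fh1_fl_fl differed between cells with the same label. The naming rule took 5 higher and 5 lower genes from this same test, so their place among the 37 was fixed in advance. Over all tested genes, 1214 of 12671 were called, so the 37 do not measure how common such differences are. Among epithelial and mesenchymal genes, the log2 fold change of clone19 against clone1 was 1.38 for Epcam, 2.14 for Esrp1, 4.09 for Mal2, 2.01 for Cldn3, -3.03 for Vim, -1.53 for Zeb1 and -3.68 for Twist2. Among antioxidant genes it was -2.39 for Gclm, -2.04 for Slc7a11, -3.88 for Gsta1 and -6.95 for Aldh3a1. Among genes of arginine metabolism it was -7.7 for Arg1, 2.2 for Arg2 and 2.44 for Ass1. For Tet2 the value was -3.67, for Hist1h2bc 1.74, for Lmod1 2.63, for Cdh5 2.15 and for Anpep -2.9. Igfbp4 gave -3.99, Ugt2b34 -5.28, Trim54 -1.95, Slc6a12 1.56, Ddr2 1.51, Lepr -1.91, Tmprss11e 3.84, Mest -1.99 and Gnai1 -5.17. By counts, clone19 was higher by ratios of 636 for Tspan6, 505 for Fam169b and 96.6 for Cdkn1c (17.3 to 3810), and at least 464-fold for Trim50, 246-fold for Sytl4 and 228-fold for Hopx. It was lower by ratios of 580 for Muc5b, 535 for Armcx3 and 526 for R3hdml.

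A single library stood apart from the other 4 of its group (gap over range above Dixon's critical ratio of 0.71) in 19 of 339 groups of named-gene values, while chance marks about 1 in 20. In clone1 replicate 1 these were Cd68 at 9.36 CPM, Ddit3 at 382, Fh1 at 123, Hmox1 at 650, Krt19 at 763 and Odc1 at 211, and in clone1 replicate 5 Ugt2b34 at 767. In clone19 they were Csf1r at 11.3 in replicate 1, Pax2 at 26.7 and Vsnl1 at 1.96 in replicate 2, Fam169b at 14.2 in replicate 3 and Hopx at 11.7 in replicate 5. In Fh1_fl_fl they were Hmox1 at 47.1 and Kdm5d at 16.8 in replicate 2 and Nt5e at 0.576 in replicate 5. In Rec they were Podxl at 192 in replicate 1, Mctp1 at 13.8 and Rrm2 at 602 in replicate 2, and Sdha at 183 in replicate 3. The flags were not spread evenly, as several fell in clone1 replicate 1. Pairs with clone1 replicate 1 had a chi-square per degree of freedom of 13.24 to 18.46, against 2.04 to 10.46 in the other clone1 pairs.

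Of 44 groups of library measures, 12 held such a library, and 8 of the 12 values belonged to clone19 replicate 3. In it, Gm42418 took 8.202% of the gene counts, Lars2 2.664%, mt-Rnr2 0.403%, mt-Rnr1 0.194% and the top 20 genes 18.68%. Its reads without a unique alignment made up 40.29%, those in no feature 6.73% and those overlapping several features 0.46%. The others were the reads overlapping several features in clone1 replicate 1 (0.65%), Lars2 in clone1 replicate 1 (0.151%) and Fh1_fl_fl replicate 3 (0.379%), and mt-Rnr2 in Fh1_fl_fl replicate 4 (0.092%).

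4 Y-linked genes had nearly all their counts in Fh1_fl_fl. Depth does not account for it, since 6 counts were seen in the 15 other libraries where 11251 were due at the Fh1_fl_fl level (0.0533%). Nor do exchanged single libraries, since over the genes outside the Y chromosome the nearest library shared the group for 20 of 20. Only 4 of the 5 tested Y genes were under 5% of the Fh1_fl_fl level. Gm47283 (90784738 to 90816464) had 7.94 CPM in Fh1_fl_fl, 15.6 in clone1, 17.3 in clone19 and 11.7 in Rec. Whether its reads come from an X-linked copy was not tested, so it cannot tell absence of the whole chromosome from a smaller loss. The other 4 genes lie close together and cannot tell these apart either. A candidate explanation is that the clones and Rec may lack the Y chromosome or a part that spans 897788 to 1286629. It may have been lost before or during cloning, and DNA was not measured. The labels do not give the cells' descent, so a Y loss and the Fh1 deletion remain joined in the comparisons of the clones with Fh1_fl_fl, while Rec, by its label, differs from Fh1_fl_fl in these genes without Fh1 deficiency.

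Fh1 counts were not clearly lower in the libraries labelled deletion, and the re-expression named by the label of Rec is not seen, since its 71.3 CPM was the lowest mean. Scaling or filtering is argued against as the cause in clone1, where the lowest log2 fold change over 18 alternatives was 0.15 and the highest 0.35. Alignment, annotation and strand setting could not be varied with the deposited counts. Exchanged single libraries are also argued against, as the nearest library shared the group for 20 of 20. Whether reads come from exons outside the deleted part cannot be told apart from an intact gene, because the 113 CPM in clone1 is a whole-gene count. The deletion itself, the biological explanation named by the labels, therefore stays open at the transcript level, and so does re-expression.

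Genes shifted together along chromosomes in the clones and also in Rec, where the spread of chromosome medians against Fh1_fl_fl was 0.143 (at most 0.042 in 1000 shuffles, permutation p = 0.001). In clone1 the median log2 fold change was 0.59 over 598 genes of chromosome 6 and -0.49 over 428 genes of chromosome 12, where Rec had 0.06 and 0.14 against Fh1_fl_fl. GC content and gene length are argued against as the whole cause, because 100% of the spread of chromosome medians in clone1 (0.248) was kept after removing their trend, and 97.2% in clone19. The spread in clone1 exceeded all 1000 shuffles of chromosome labels (permutation p = 0.001, the smallest they can give, with 0.063 the highest shuffled). The genes of chromosome 6 in order were divided in 2 sets of 299. Their medians were 0.41 and 0.81 in clone1 and 0.25 and 0.35 in clone19. In clone19 the whole chromosome (0.3) was also the highest, but X (0.26) and chromosomes 14 (0.24) and 9 (0.23) were close. A gain of chromosome 6 in the clones, which Rec would then lack, may explain the shift. Because the sets differed in clone1, the medians cannot tell a gain of the whole chromosome from one of a part. Copy number was not measured, and a regulatory cause stays open.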

How the results depend on the processing

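The alternative without Gm42418, Lars2, mt-Rnr1 and mt-Rnr2, DESeq2 for named genes, the alternatives for differences between the clones and the share undone with divided clone replicates were chosen after the data were seen. No named gene or list that was called in the main fit or in an alternative reversed between them. Results called in neither were not counted here, and their sign can differ. The near-even majority of changed genes turned under some alternatives. In clone1 against Fh1_fl_fl it went from lower to higher. From higher to lower it went in clone19 against Fh1_fl_fl, Rec against clone1 and clone19 against clone1. The 4-group fit and the fit of only the groups compared are the same for returned genes, which therefore have no separate value there.

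Genes changed numbered 8633 to 11233 in clone1 against Fh1_fl_fl over the alternatives, 8053 to 10232 in clone19, 8628 to 10942 and 8208 to 10371 in Rec against clone1 and clone19, 7823 to 9537 in Rec against Fh1_fl_fl, and 7003 to 8802 between the clones. Over 2-fold calls ran in that order from 2029 to 3439, 1363 to 2461, 2110 to 3242, 1397 to 2359, 1008 to 1657 and 833 to 1423. The highest values came without the count filter, and the lowest with a filter of 5 CPM in 5 libraries or an adjusted p under 0.01, which test fewer genes or ask more of each by construction. Genes shared by the clones were 953 to 6797, with 6797 when no fold bound was set, and returned genes 585 to 1055, with 585 when over 2-fold was required in Rec against both clones, both by construction. Leaving out each library in turn gave 9778 to 9958, 9017 to 9224, 9708 to 9879, 9143 to 9355, 8642 to 8821 and 7949 to 8312 changed genes in the same order, and 2722 to 2769, 1925 to 1978, 2713 to 2820, 1904 to 1992, 1342 to 1415 and 1191 to 1231 over 2-fold. It gave 1297 to 1354 shared and 966 to 1016 returned genes, and 36 to 38 named genes differing between the clones (37 with all libraries, 35 to 38 over all alternatives). Choosing shared genes on other clone libraries than those compared with Rec gave 1277 shared and 884 returned genes. With the replicate number as a block, although the numbers do not pair the samples, 9926, 9186, 9837, 9310, 8918 and 8172 genes changed, 1329 were shared and 997 returned.

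Called lists depended most on the test. Fry, which asks whether a list's genes move one way and not whether they differ from other genes, called 23, 21, 24, 22, 23 and 22 lists in the same order. Camera with an estimated correlation called 4 in clone19 against Fh1_fl_fl, 5 and 3 in Rec against clone1 and clone19, and 1 between the clones, beside 6 in clone1 and 5 in Rec against Fh1_fl_fl; the cause was not tested. Without single libraries camera called 9 to 9, 9 to 10, 8 to 9, 8 to 8, 7 to 10 and 6 to 8 lists. Of the comparisons of single lists with an alternative, 2795 kept their side of the threshold, 121 gained a call and 29 lost it, and for named genes 12250, 71 and 71. Scaled to library totals, 36.55% of the genes changed in Rec against Fh1_fl_fl were higher, in place of 47.16%, and 40.1 and 40.68% in clone1 and clone19, in place of 48.42 and 50.47%.

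Other splits of the 10 libraries into 5 and 5 asked whether the group labels could be exchanged. For the 2 groups fitted alone, edgeR called 9715, 9069, 9313, 8889, 9064 and 7510 genes in the real split, and 0 in every other of 100 splits, where at most 3346, 3216, 3680, 3968, 3852 and 3179 had an unadjusted p under 0.05. For over 2-fold it called 2626, 1830, 2532, 1690, 1327 and 1068 against 0. So 1 of 100 splits, the real one, gave as many, and 1 of 50 for the 1312 shared and 999 returned genes, with 0 in the others. Every other split mixes the groups, so their difference widens the spread within each set, and the 0 there is no measure of noise. The rank shows only that the labels cannot be exchanged, not how many calls noise alone would give. The number of called lists cannot tell, because every other split of 5 and 5 holds the groups in unequal numbers and so keeps part of the real contrast. The real splits gave 9, 10, 8, 8, 7 and 8, and 45, 8, 59, 51, 48 and 13 of 100 splits gave as many, up to 12, 11, 13, 12, 10 and 10.

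Depth limits the genes near 0, where 3 counts in 1 library correspond to 0.158 to 0.501 CPM, and 26508 genes had too few counts to be tested.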

Other observations

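The recount without genes near the 4 seen first was chosen after the result was seen.

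Peg3, Mest, Grb10 and Cdkn1c, which are expressed from 1 parental copy, were near 0 in Rec, and this led to the hypothesis that imprinted genes as a class may have been silenced there. Of 43 imprinted genes listed from general knowledge, 24 were tested and 11 were over 2-fold lower in Rec than in Fh1_fl_fl. Leaving out the 4 seen first, 7 of 20 were lower and 0 higher by edgeR, against a mean of 1.86 and a 95th percentile of 4 in 10000 random lists matched on expression (permutation p = 8e-04). Several of the 7 lie beside those 4 and are not independent of them, as Usp29 and Zim1 near Peg3 and Kcnq1 near Cdkn1c. Without listed genes within 5 Mb of the 4, 4 of 13 were lower (Ndn, Plagl1, Sgce and Zrsr1), against a mean of 0.96 and a 95th percentile of 3 (permutation p = 0.0075). Some of these 13 are also neighbours of each other, while the random lists drew genes singly, so both permutation p-values may be too small. Ndn had 9.4 CPM in Fh1_fl_fl, 21.18 in clone1, 7.03 in clone19 and 0.04 in Rec. Plagl1 had 3, 0, 4.78 and 0 CPM in that order, Zrsr1 19.32, 98.33, 11.76 and 5.65, and Sgce 65.39, 44.94, 43.43 and 27.97. Zim1 had 28.29, 1.21, 0.68 and 0.05 CPM, and Kcnq1 3.75, 0.47, 0.91 and 0.03. Usp29 had 0.26 CPM in Fh1_fl_fl, 4.41 in clone1, 3.34 in clone19 and 0 in Rec. Peg10 went the other way, from 31.9 CPM in Fh1_fl_fl to 67.39 in Rec (log2 fold change 1.09), a change that the test against 2-fold did not call (adjusted p = 0.552). Of the 11, Grb10, Zim1, Cdkn1c, Kcnq1 and Mest were also over 2-fold lower in both clones than in Fh1_fl_fl, and Plagl1 in clone1, so much of the pattern is not particular to Rec. Cdkn1c had 10.23, 0.02, 2.11 and 0.08 CPM in the same order, Mest 25.81, 11.05, 2.76 and 0, and Grb10 22.06, 0.37, 0.26 and 0. Gene counts cannot separate loss of the active copy from a change of methylation, and since the labels do not give the descent of Rec, a subclone that differed beforehand stays open.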
